A study of Mus musculus with 4 samples.

How the data were processed

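RNA sequencing had been done on tumour-infiltrating T cells of C57BL/6 mice, taken 21 days after tumour inoculation. The cells came from wild-type mice or, per the labels, from mice with a knockout of Map4k1, the gene for haematopoietic progenitor kinase 1 (HPK1). Map4k1 transcript was reduced but not absent in the libraries labelled knockout. Each genotype had 2 libraries, made per the labels from Trizol-extracted RNA with the NEBNext Ultra RNA kit. The labels did not name the tumour, the gate used to isolate T cells or the knockout allele. They also did not say whether the 2 libraries of a genotype came from separate mice. The p-values therefore measure only the spread between these libraries, which may be technical. The library descriptions shared a common run tag, so no sequencing batch could be separated in the labels.

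The authors deposited a table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of a library), with 1 row per Ensembl gene and 1 column per library. The submitters' processing notes named HISAT, a spliced aligner, and Cuffnorm, which computes and scales FPKM across libraries, and the mouse build GRCm38. Versions, the annotation, the strand setting and the scaling option were not given in the sources used here. The table held 21146 genes, each above 0 in at least 1 library. Symbols and positions were taken from GENCODE M21 on GRCm38 for 21011 of the gene IDs, and 135 had no match.

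Fragment counts were not part of the table, but low FPKM values fell on regular steps. Of the low values, 90.5% to 91.6% per library lay within 0.1 of a whole number of fragments. This used only genes with a single annotated transcript of 1000 to 6000 nt, less a mean fragment length of 260 nt. That length and the scale were chosen to give the sharpest steps in these same values, so part of this agreement is built in. The steps gave an approximate scale of 21700000 and 20200000 fragments for the wild-type libraries and 22600000 and 23200000 for the knockout libraries. A single fragment in a 2-kb gene was then worth 0.0247 to 0.0284 FPKM. On this scale the 2 libraries of a genotype differed by more than sampling noise, with a chi-square per degree of freedom of 12.4 for wild type and 5.86 for knockout. The columns of a pair were therefore not copies, but a second preparation of the same RNA could differ as much. FPKM totals were 975047 and 975107 in wild type and 871584 and 878585 in knockout.

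Values were transformed as log2(FPKM + 1), and genes with at least 1 FPKM in at least 2 of the 4 libraries were tested, 11947 in all. Fold changes are on this scale, knockout minus wild type, which understates the change of low genes. The test was limma's moderated linear model with a mean-variance trend and empirical Bayes variances (limma 3.58.1 in R 4.3.3), two-sided. Benjamini-Hochberg adjustment was applied over all tested genes, with a threshold of 0.05. Residual degrees of freedom were 2 and the estimated prior degrees of freedom 3.39. Lists of genes, 36 in all, were fixed from general knowledge and tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 35 lists with a tested member. Camera compares a list with all other genes. Some genes belong to several lists, so the lists are not separate pieces of evidence. The lists were also tested with an estimated correlation and with fry, which tests whether a list's genes moved on balance in a single direction without comparing them with other genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

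The genes named in the text followed a rule with 4 parts. Map4k1 came first. The second part took up to 12 genes per direction with the largest fold changes among genes past the threshold, with a mean of at least 5 FPKM in the higher genotype and no overlap between genotypes. Predicted genes, RIKEN clones, pseudogenes and immunoglobulin or T cell receptor segments were left out of that part. The third part took from each list up to 4 members past the threshold with the lowest p, or the 2 lowest if none passed. The fourth part was a set of 17 genes fixed by name, from Pdcd1 and Havcr2 to Foxp3. The rule selected 139 genes, and 3 of them were not used here. The design, lists, rule and alternatives were fixed before the data were examined. Genes outside the rule are said to have been chosen after their values were seen, or belong to the tests that close the text, whose timing is given there.

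Alternatives covered the pseudocount, the filter on low values, quantile normalization, median-of-ratios scaling, and scaling to equal totals without mitochondrial, haemoglobin and immunoglobulin genes. They also covered limma without the trend and with robust variances, other thresholds, the replicate number as a block, and leaving out each library in turn. When a library was left out, the lone library of its genotype was assumed to vary like the other pair. A fit after removal of a trend on transcript length and GC content per library, by loess with a span of 0.5, was added after seeing the data. The limma and camera steps were tested on simulated data with the real means and residual spreads, with 200 of the 11947 genes changed in each of 5 runs. In this simulation of the knockout against wild type comparison, 0.597% of genes changed by 0.5 on the log2 scale were recovered, 46.6% of those changed by 1 and 79.7% of those changed by 2. Of all calls in it, 2.77% were unchanged genes. A list shifted by 0.5 was called in 5 of 5 runs, and no unshifted list was. Genes were simulated independently of each other, so these runs do not show how camera behaves when genes of a list are correlated.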

Results

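Gene expression was measured by RNA sequencing in T cells isolated from mouse tumours 21 days after inoculation, in 2 libraries from wild-type mice and 2 from Map4k1 knockout mice. Values were FPKM, as the authors deposited them, for 21146 genes. Between 11609 and 11825 genes per library reached 1 FPKM. The steps between low values put the scale of the 4 libraries at about 20200000 to 23200000 fragments, similar in both genotypes. The scaling option of Cuffnorm was not given, so this scale need not equal the sequencing depth. The 10 most abundant genes took 6.47% to 7.56% of a library's FPKM. Across the 11947 tested genes, the correlation of log2(FPKM + 1) was 0.986 between the wild-type libraries and 0.992 between the knockout libraries. It was 0.958 to 0.964 for the 4 pairs of different genotype. The first principal component held 74.5% of the variance and separated the genotypes, and the second, with 16.0%, separated the wild-type libraries from each other.

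The design has a single comparison, knockout against wild type. Map4k1 encodes HPK1, a serine/threonine kinase of blood cells that acts as a brake on T cell receptor signalling. The comparison addresses which genes of tumour-infiltrating T cells, among them those of T cell function and exhaustion, differ between libraries labelled knockout for this kinase and wild-type libraries. Map4k1 itself (ENSMUSG00000037337, GRCm38 chromosome 7, 28982050 to 29003279, plus strand, protein coding) was at 48.9 and 41.2 FPKM in wild type and at 20.6 and 26.5 FPKM in the knockout libraries. It fell by 0.91 on the log2 scale (SE 0.15, limma adjusted p = 0.0134) and was lower in both knockout libraries, but transcript remained. The values are per gene and the labels did not describe the allele, so they do not show whether the remaining transcript included the targeted exons. The adjusted p was 0.0634 without knockout replicate 1, and 0.0764 when all 21146 genes were tested without a filter.

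In the knockout libraries 13 of 16 tested cytokine genes and 8 of 9 tested chemokine genes fell, and 43 of 44 tested cell cycle genes rose. Each of these 3 lists had a camera adjusted p = 0.185 with an estimated correlation, a setting with little power at 2 residual degrees of freedom. Of the 11947 genes, 3390 (28.4%) passed the threshold, with 1839 higher and 1551 lower in the knockout. The large changes were mostly decreases, since 394 of the lower genes and 114 of the higher genes changed at least 2-fold. Genes past an unadjusted p of 0.05 numbered 5157. The values of the genotypes did not overlap for 70.0% of the tested genes, where chance gives 33.3% with 2 libraries against 2. No single-gene permutation test can go below p = 0.333 in this design, so all calls rest on variance shared across genes in limma. Fewer genes passed when a knockout library was left out, 579 without replicate 1 and 945 without replicate 2, and 1231 passed when low genes were not filtered. Scaling to equal totals raised the median fold change of all genes by 0.142 and gave 3475 higher and 1118 lower genes, 75.7% of calls higher in place of 54.2%. Median-of-ratios scaling turned the balance the other way, with 1527 higher and 1726 lower genes, 46.9% of calls higher. Predicted genes, RIKEN clones, pseudogenes and antigen receptor segments made up 219 of the higher and 220 of the lower genes.

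**Figure D1:**
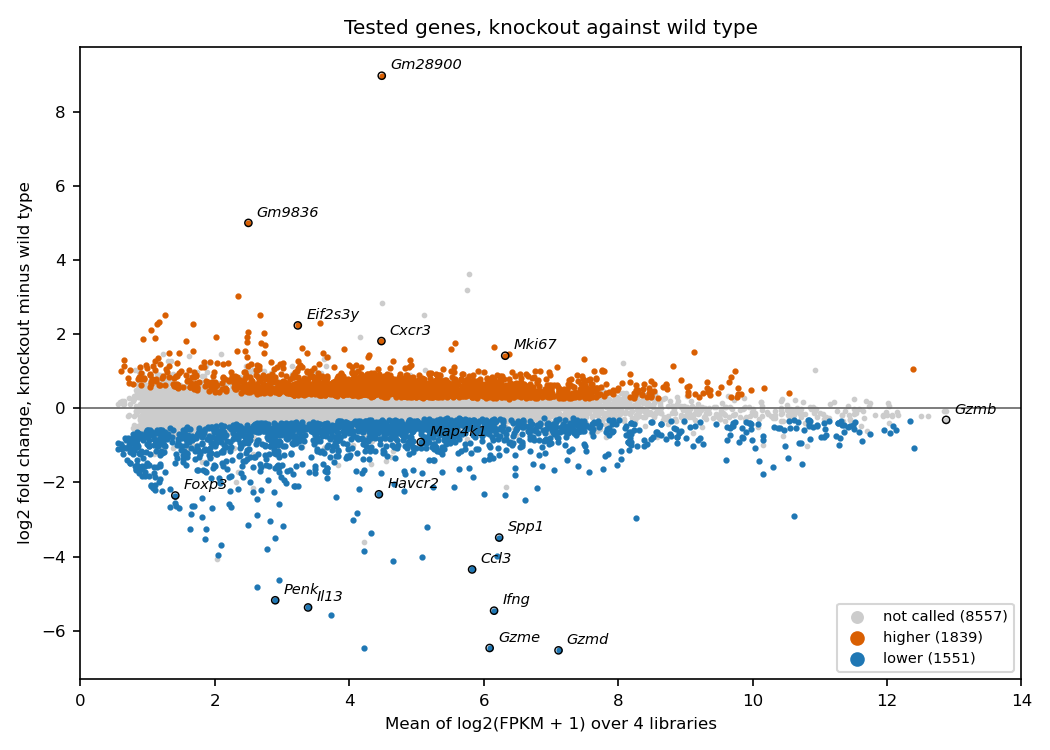
Each point is 1 of the 11947 tested genes, with the mean of log2(FPKM + 1) over the 4 libraries on the horizontal axis and the log2 fold change, knockout minus wild type, on the vertical axis, coloured orange for the 1839 higher and blue for the 1551 lower genes at a limma adjusted p below 0.05 and grey for the rest. Gzmd, Gzme and Ifng lie more than 5 units below 0 while the abundant Gzmb lies near 0. The 2 highest points are the processed pseudogenes Gm28900 and Gm9836, listed at 0 in both wild-type libraries and chosen after their values were seen.

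Among the named genes, the deepest falls on the log2(FPKM + 1) scale were in granzymes, the serine proteases of cytotoxic granules. The ratio of mean FPKM was larger for some less abundant genes, such as Ccl22 (270.7) and Penk (183.5), than for any named granzyme. Gzmd went from 1331 ± 102 FPKM (SD, n = 2) in wild type to 13.5 ± 1.78 FPKM in the knockout, a log2 fold change of -6.53 (SE 0.11, adjusted p = 2.93e-05). Gzme fell from 639 ± 26.2 to 6.28 ± 1.04 FPKM, Gzmg from 173 ± 9.14 to 0.984 ± 0.167 FPKM, and Gzmf from 90.4 ± 6.16 to 0.959 ± 0.504 FPKM. These are near-identical neighbours on chromosome 14, and how the authors' counting divided shared reads among them is uncertain. The more distinct Gzmc fell from 859 ± 8.63 to 110 ± 0.776 FPKM, and Prf1, the pore-forming perforin, from 231 ± 2.49 to 40.6 ± 3.09 FPKM. Gzmb, the most abundant granzyme, did not pass, at 8412 ± 228 and 6768 ± 138 FPKM (log2 fold change -0.31, SE 0.09, adjusted p = 0.0543). Of the 21 tested genes of the cytotoxic granule and effector list, 12 fell and 1 rose (15 fell and 1 rose when adjusted over the list alone). The list was called lower by camera (adjusted p = 2.58e-07). Its adjusted p was 0.185 with an estimated correlation. The member that rose was Ctsw, a cathepsin of cytotoxic cells, at 109 ± 1.68 and 138 ± 0.59 FPKM, and its adjusted p of 0.0248 was as high as 0.184 with a single knockout library left out.

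Most tested cytokine and chemokine genes also fell. Ifng, the gene for interferon gamma, went from 471 ± 9.54 to 9.75 ± 0.685 FPKM, a log2 fold change of -5.46 (SE 0.08, adjusted p = 2.93e-05) and a 48.3-fold lower mean. Il13, a type 2 cytokine, fell from 66.3 ± 1.64 to 0.626 ± 0.0179 FPKM, and Csf2, the gene for GM-CSF, from 69.9 ± 9.62 to 3.91 ± 0.252 FPKM. Tnf fell less, from 47.2 ± 2.80 to 37.6 ± 1.90 FPKM (log2 fold change -0.32, SE 0.09, adjusted p = 0.049), and lost its call without any 1 of the 4 libraries, with adjusted p up to 0.285. Il2 was under the filter, at 0.779 and 0.726 FPKM in wild type and listed at 0 in both knockout libraries. Of 16 tested T cell cytokine genes, 13 fell and none rose (14 and 0 adjusted over the list alone), and camera called the list lower (adjusted p = 3.77e-10, and adjusted p = 0.185 with an estimated correlation). Of 9 tested chemokine genes, 8 fell and none rose (8 and 0 adjusted over the list alone), with a median log2 fold change of -3.94 (camera adjusted p = 1.89e-09, and adjusted p = 0.185 with an estimated correlation). Ccl3 and Ccl4, which attract leukocytes, fell from 255 ± 12.3 to 11.6 ± 0.403 FPKM and from 291 ± 11.3 to 17.5 ± 0.670 FPKM. Ccl1 fell from 104 ± 3.16 to 5.04 ± 0.868 FPKM, and Xcl1, which attracts cross-presenting dendritic cells, from 135 ± 13.0 to 7.54 ± 1.13 FPKM. Ccl9 was at 35.3 and 28.4 FPKM in wild type and at 0.323 and 0.0312 FPKM in the knockout. Ccl22 was at 14.8 and 15.7 FPKM against 0.0908 and 0.022 FPKM. Outside these lists, Penk, which encodes the enkephalin precursor, fell from 43.8 ± 0.259 to 0.239 ± 0.0204 FPKM, and Serpinb9b, of the family of granzyme inhibitors, from 37.8 ± 0.0972 to 0.559 ± 0.121 FPKM.

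**Figure D2:**
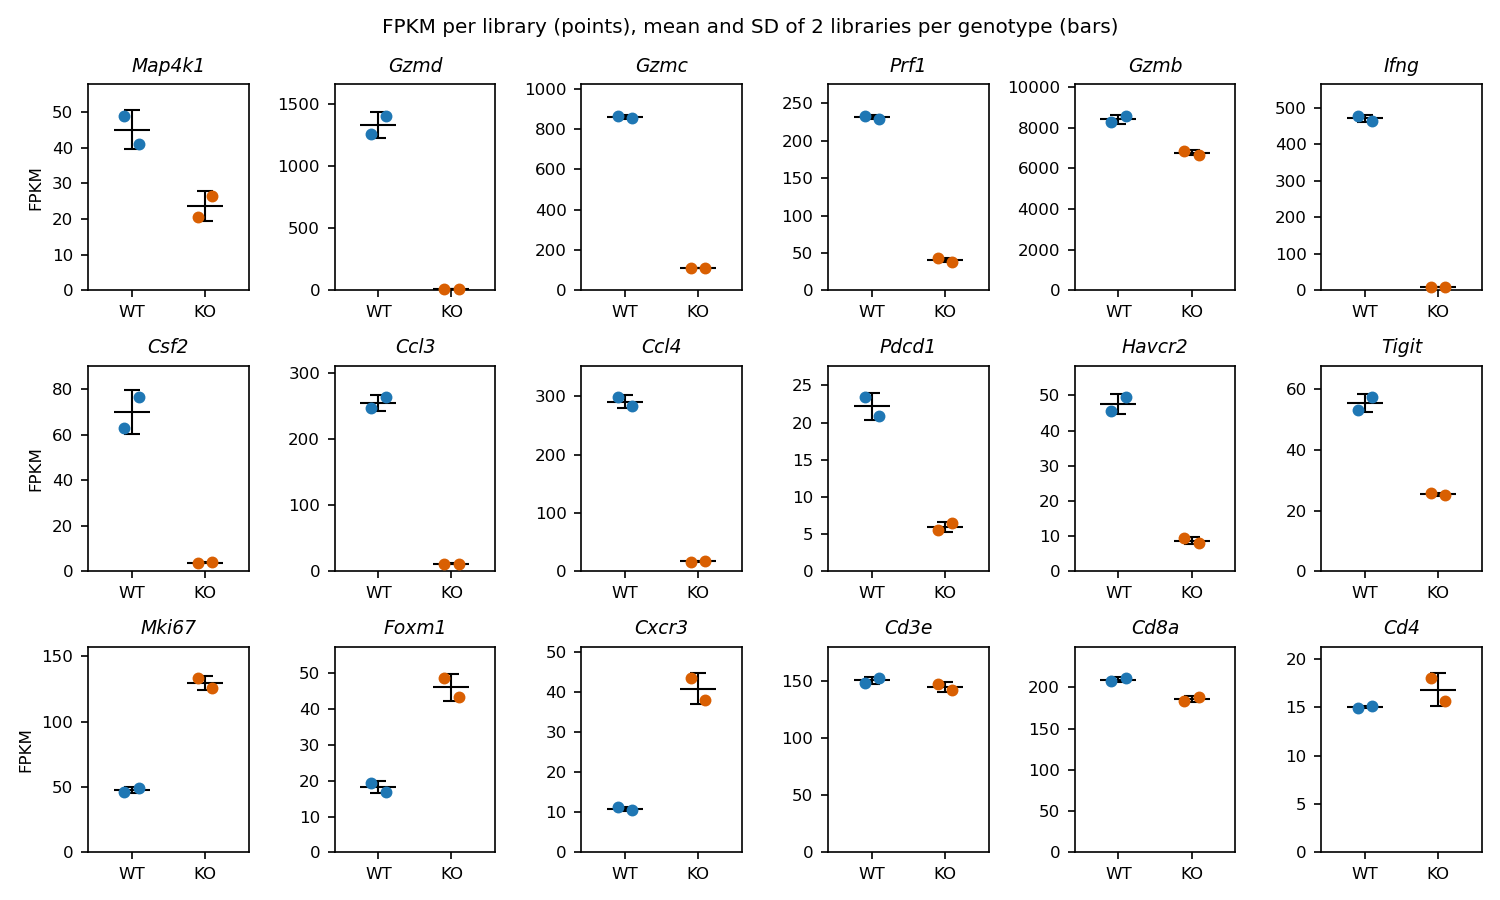
FPKM of 18 genes in each library, with blue points for the 2 wild-type (WT) and orange points for the 2 Map4k1 knockout (KO) libraries; black bars give the mean and SD of each genotype, and every vertical axis starts at 0. Gzmd, Ifng, Csf2, Ccl3 and Ccl4 are near 0 in both knockout libraries, Mki67, Foxm1 and Cxcr3 are higher in both, and Cd3e, Cd8a and Cd4, which did not pass the test, have similar levels.

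Most tested genes of the inhibitory receptor and exhaustion list fell. Havcr2, which encodes TIM-3, fell from 47.6 ± 2.78 to 8.74 ± 0.944 FPKM (log2 fold change -2.32, SE 0.11, adjusted p = 0.000676), and Pdcd1, which encodes PD-1, from 22.2 ± 1.80 to 6.03 ± 0.672 FPKM (log2 fold change -1.72, SE 0.12, adjusted p = 0.00191). Lag3 fell from 39.5 ± 4.20 to 19.1 ± 1.91 FPKM, Tigit from 55.2 ± 2.99 to 25.4 ± 0.517 FPKM, and Ctla4 from 45.4 ± 4.95 to 19.4 ± 0.476 FPKM. The nuclear receptors Nr4a2 and Nr4a3, which are induced by receptor stimulation, fell from 6.97 ± 0.210 to 1.175 ± 0.249 FPKM and from 15.7 ± 0.376 to 3.13 ± 0.159 FPKM. Of the 24 tested genes of the inhibitory receptor and exhaustion list, 17 fell and 1 rose (19 and 1 adjusted over the list alone). Camera called the list lower (adjusted p = 3.77e-10), and its adjusted p was 0.185 with an estimated correlation. Prdm1, the gene for BLIMP-1, did not pass, at 7.17 and 8.53 FPKM in wild type and 5.96 and 4.97 FPKM in the knockout (adjusted p = 0.0627).

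Many tested genes of the NF-kappa B list and of the MAPK and AP-1 list fell, and others did not pass. Of 28 tested genes of the NF-kappa B pathway and its targets, 16 fell and none rose (16 and 0 adjusted over the list alone, camera adjusted p = 3.63e-07, and adjusted p = 0.185 with an estimated correlation). Tnfaip3, the gene for the ubiquitin-editing enzyme A20, fell from 15.5 ± 1.20 to 3.84 ± 0.0342 FPKM, and Traf1 from 107 ± 5.59 to 50.3 ± 0.498 FPKM. Bcl2a1d and Bcl2a1b, near-identical survival genes whose shared reads make each value uncertain, fell from 45.2 ± 6.17 to 5.52 ± 0.803 FPKM and from 97.7 ± 10.5 to 21.6 ± 2.84 FPKM. Of 29 tested genes of the MAPK cascade and AP-1, 15 fell and 1 rose (16 and 2 adjusted over the list alone, camera adjusted p = 0.000615, and adjusted p = 0.204 with an estimated correlation). Among them Egr1, an immediate early transcription factor, fell from 31.1 ± 0.538 to 5.09 ± 0.147 FPKM. The ERK phosphatase genes Dusp2 and Dusp5 fell from 109 ± 12.2 to 29.2 ± 0.460 FPKM and from 111 ± 5.29 to 43.0 ± 1.02 FPKM. Egr3, a further early response factor, fell from 11.02 ± 0.490 to 3.10 ± 0.301 FPKM. Of 34 tested genes of the T cell receptor complex and its proximal signalling, 7 rose and 3 fell (11 and 6 adjusted over the list alone), and the list was not called (camera adjusted p = 0.22). Trat1, an adaptor of the receptor complex, fell from 6.41 ± 1.10 to 1.78 ± 0.485 FPKM. Grap2, an adaptor that binds SLP-76, rose from 64.1 ± 2.05 to 97.2 ± 4.67 FPKM, the adhesion receptor gene Cd2 rose from 171 ± 8.65 to 250.2 ± 8.97 FPKM, and Cblb, a ubiquitin ligase that restrains signalling, fell from 35.4 ± 3.25 to 21.4 ± 0.886 FPKM. These 3 calls were lost without knockout replicate 1, with adjusted p up to 0.0773. Cd3e was at 151 ± 3.07 and 145 ± 4.22 FPKM and did not pass (adjusted p = 0.594).

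Nearly all tested cell cycle genes rose. Of 44 tested genes of the cell cycle and proliferation list, 43 rose and none fell (43 and 0 adjusted over the list alone), with a median log2 fold change of 0.77. Camera called the list higher (adjusted p = 2.93e-18), and its adjusted p was 0.185 with an estimated correlation. It was the only list called higher. Mki67, which encodes the proliferation antigen Ki-67, rose from 47.9 ± 2.23 to 129.6 ± 5.46 FPKM (log2 fold change 1.42, SE 0.08, adjusted p = 0.00114). The replication helicase gene Mcm3 rose from 79.5 ± 0.306 to 160.4 ± 3.09 FPKM, the spindle genes Kif11 and Tpx2 from 27.4 ± 1.13 to 53.2 ± 0.0396 FPKM and from 36.7 ± 1.11 to 70.2 ± 1.183 FPKM. Foxm1, a transcription factor of the G2/M programme, rose from 18.2 ± 1.76 to 46.1 ± 3.75 FPKM, and Hirip3, a histone chaperone gene, from 49.0 ± 0.120 to 137 ± 2.97 FPKM. Replication-dependent histone genes were among the 12 largest rises, led by Hist1h2ah at 1.74 and 4.02 against 8.34 and 14.5 FPKM and with Hist1h2ag at 114 ± 25.2 against 284 ± 36.5 FPKM. Copies of this histone are near-identical, so their single values are uncertain. The call of Hist1h2ah was lost without wild-type replicate 1 or knockout replicate 2, and that of Hist1h2ap (adjusted p = 0.029) without either knockout library, with adjusted p up to 0.0825 and 0.105. Hist1h2ap was at 480.7 and 224.9 against 990.1 and 899.0 FPKM. Hist1h2af rose from 5.26 ± 1.52 to 16.5 ± 1.36 FPKM.

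Receptors for migration and markers of memory changed in both directions. Cxcr3, the chemokine receptor for interferon-induced ligands, rose from 10.9 ± 0.504 to 40.9 ± 3.84 FPKM (log2 fold change 1.81, SE 0.10, adjusted p = 0.00112), while Ccr7, the lymph node homing receptor, fell from 39.4 ± 0.564 to 11.1 ± 0.566 FPKM. Ly6c1 and Ly6c2, similar genes of a memory cell surface antigen, rose from 602 ± 81.3 to 1208 ± 129 FPKM and from 611 ± 13.8 to 1104 ± 39.2 FPKM. Tcf7, which encodes the stem-like T cell factor TCF-1, was at 18.4 ± 0.0729 and 20.2 ± 0.698 FPKM and did not pass (adjusted p = 0.3). Of 25 tested genes of the naive, memory and stem-like list, 4 rose and 4 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.55). Of 22 tested trafficking and residence genes, 4 rose and 7 fell (5 and 9 adjusted over the list alone, camera adjusted p = 0.164). Rgs1, which dampens chemokine receptor signalling, fell from 107 ± 13.2 to 11.1 ± 3.81 FPKM, and the hyaluronan receptor gene Cd44 from 52.4 ± 5.14 to 26.5 ± 0.166 FPKM. Of 19 tested costimulatory receptor and activation genes, 6 fell and 2 rose (9 and 4 adjusted over the list alone). Crtam fell from 14.1 ± 0.785 to 3.15 ± 0.378 FPKM, Tnfrsf9, which encodes 4-1BB, from 649 ± 33.7 to 341 ± 20.7 FPKM, and Tnfrsf18, which encodes GITR, from 167 ± 10.2 to 94.4 ± 0.492 FPKM. That list was called lower by camera (adjusted p = 0.0346), with an adjusted p of 0.427 with an estimated correlation, 0.111 without wild-type replicate 2 and 0.0586 without knockout replicate 2.

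**Figure D3:**
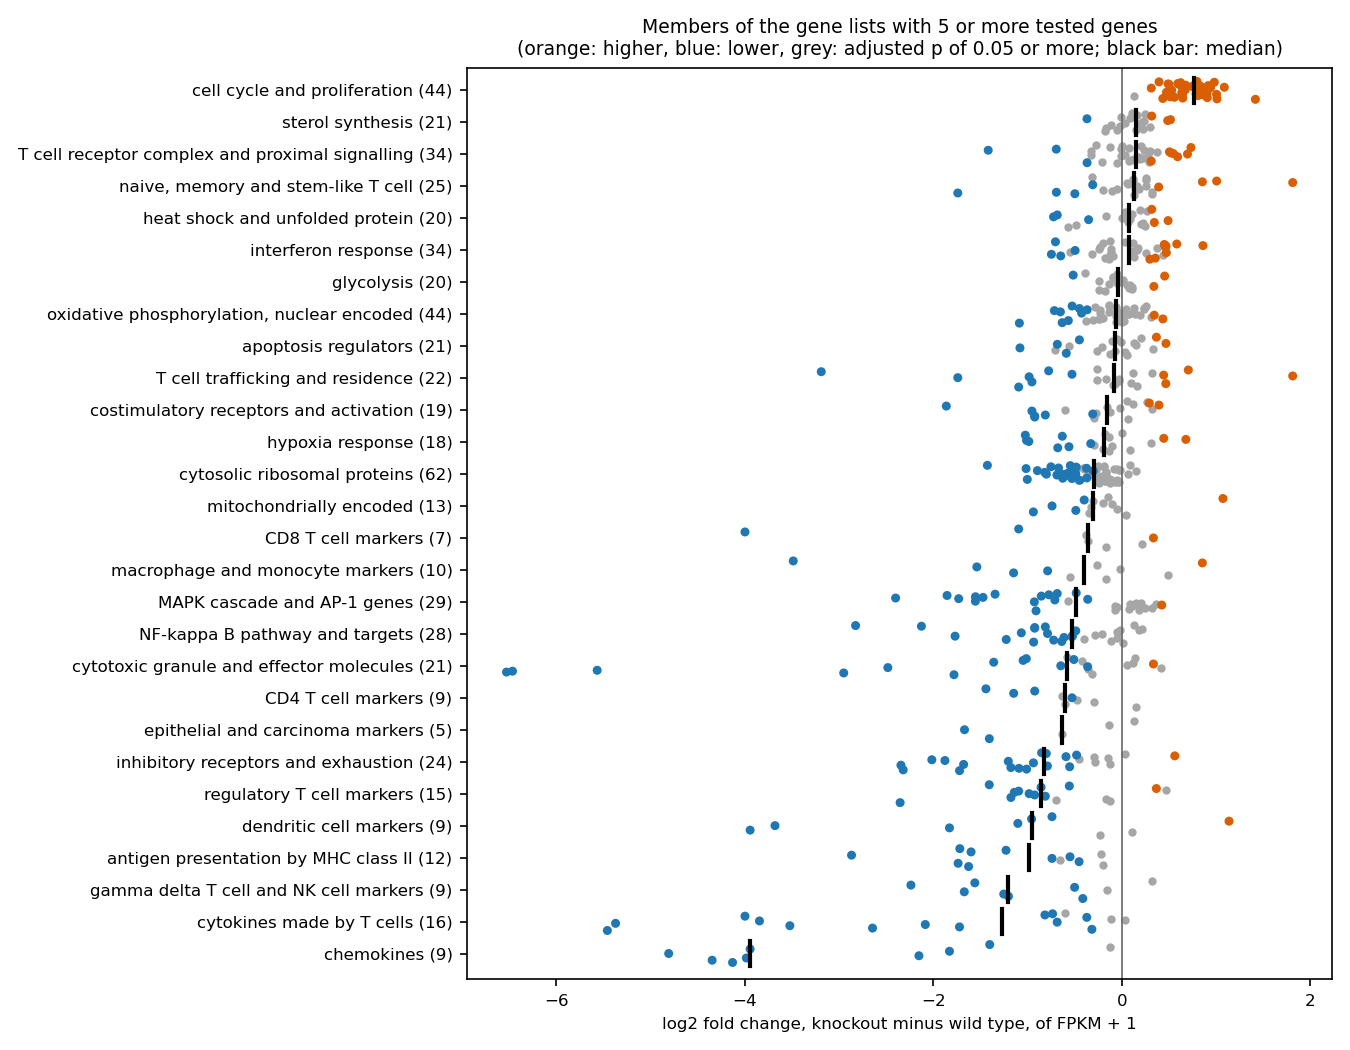
Log2 fold change, knockout minus wild type, of every tested member of the gene lists with at least 5 tested genes, with the number tested after each name; orange and blue points are genes higher and lower at a limma adjusted p below 0.05, grey points did not pass, and black bars are medians. The cell cycle list lies to the right of 0 with a median of 0.77, and the chemokine, cytokine, granule and inhibitory receptor lists lie to the left.

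Markers of T cell subsets and of other cells were followed as measured facts beside these groups. Some of them were also counted in lists above, such as Ctla4, Tnfrsf9 and Tnfrsf18 of the regulatory T cell list. Cd8a was at 210 ± 2.74 and 186 ± 3.50 FPKM (adjusted p = 0.13) and Cd4 at 15.01 ± 0.119 and 16.8 ± 1.72 FPKM (adjusted p = 0.319), and neither passed. Of 7 tested CD8 T cell markers, 2 fell and 1 rose (2 and 2 adjusted over the list alone, camera adjusted p = 0.133). Itgae, which encodes the integrin CD103, fell from 1.505 ± 0.179 to 0.171 ± 0.0215 FPKM. Of 9 tested CD4 T cell markers, 4 fell and none rose (8 and 0 adjusted over the list alone, camera adjusted p = 0.000498, and adjusted p = 0.206 with an estimated correlation). The members that fell included Gata3, the type 2 lineage factor, from 16.0 ± 0.394 to 6.70 ± 0.587 FPKM, Izumo1r, which encodes folate receptor 4, from 21.6 ± 3.50 to 7.27 ± 0.468 FPKM, and Tnfrsf4, which encodes OX40, from 47.6 ± 1.57 to 24.6 ± 1.41 FPKM. Cxcr6, a chemokine receptor of resident cells, fell from 64.2 ± 5.54 to 44.1 ± 0.0548 FPKM, and its call and that of Itgae were lost without either knockout library, with adjusted p up to 0.0963. Of 15 tested regulatory T cell markers, 10 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 4.36e-05, and adjusted p = 0.186 with an estimated correlation). Foxp3, the lineage factor of regulatory T cells, fell from 5.02 ± 0.527 to 0.178 ± 0.0707 FPKM. Capg, an actin-capping gene used as a marker of these cells, fell from 246 ± 26.9 to 92.0 ± 7.29 FPKM. Of 9 tested gamma delta T cell and NK cell markers, 7 fell and none rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.000498, and adjusted p = 0.36 with an estimated correlation). Fcer1g, a signalling adaptor of innate-like lymphocytes, fell from 60.0 ± 5.35 to 11.9 ± 1.53 FPKM, Klrb1c, which encodes NK1.1, from 14.6 ± 0.184 to 3.88 ± 0.101 FPKM, and the gamma chain constant segment Tcrg-C2 from 33.5 ± 3.92 to 13.95 ± 0.476 FPKM. A second gamma constant segment, Tcrg-C4, fell from 4.87 ± 0.813 to 1.46 ± 0.292 FPKM.

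Some genes usually tied to antigen-presenting cells were low and fell. Of 12 tested genes of MHC class II presentation, 9 fell and none rose (10 and 0 adjusted over the list alone, camera adjusted p = 2.45e-06, and adjusted p = 0.185 with an estimated correlation). Cd74, the invariant chain, fell from 15.7 ± 1.26 to 1.31 ± 0.451 FPKM, H2-Eb1 from 2.89 ± 0.291 to 0.166 ± 0.0296 FPKM, and the costimulatory ligand gene Cd80 from 21.1 ± 1.27 to 6.30 ± 0.599 FPKM. Cd40, a receptor of antigen-presenting cells, was at 2.15 and 2.94 FPKM in wild type and at 0.0333 and 0.107 FPKM in the knockout (adjusted p = 0.00548). Of 9 tested dendritic cell markers, 6 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.000884, and adjusted p = 0.206 with an estimated correlation). Ccl17 and Ccl22 counted both here and in the chemokine list. Fscn1, an actin-bundling gene of mature dendritic cells, fell from 14.3 ± 1.09 to 0.189 ± 0.00955 FPKM, and Ccl17 was at 2.09 and 3.09 FPKM in wild type and listed at 0 in both knockout libraries. Irf8, a transcription factor of dendritic cells that T cells also express, fell from 132 ± 8.37 to 67.2 ± 1.96 FPKM. Of 10 tested macrophage and monocyte markers, 4 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.0267, and adjusted p = 0.427 with an estimated correlation), and the call ended without wild-type replicate 2 (adjusted p = 0.0522). Some of the members that moved, such as Spp1 and Ctsd, are also used by T cells, and which cells were their source here was not tested. Spp1, the gene for osteopontin, fell from 250.5 ± 2.46 to 21.4 ± 1.00 FPKM, and Ctsd, a lysosomal protease gene, from 479.7 ± 15.2 to 277 ± 5.85 FPKM. Cebpb, a transcription factor of myeloid cells, fell from 10.6 ± 3.27 to 4.13 ± 0.316 FPKM, a call lost without either knockout library (adjusted p up to 0.0784). Both tested mast cell and basophil genes fell, Mcpt8 from 5.69 ± 0.261 to 0.074 ± 0.00177 FPKM and Kit from 5.32 ± 0.373 to 1.01 ± 0.540 FPKM (2 of 2 adjusted over the list alone, camera adjusted p = 0.00939, and adjusted p = 0.254 with an estimated correlation). All 3 tested erythroid genes fell (3 adjusted over the list alone, camera adjusted p = 0.0155, and adjusted p = 0.376 with an estimated correlation), among them Hba-a1 from 4.72 ± 0.0155 to 2.32 ± 0.341 FPKM, and its near-identical copy Hba-a2, which shares its reads, from 4.85 ± 0.680 to 2.12 ± 0.267 FPKM. The beta globin gene Hbb-bt fell from 1.88 ± 0.791 to 0.248 ± 0.0645 FPKM. The 3 calls of erythroid genes were lost without either knockout library, with adjusted p up to 0.0943.

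The remaining marker lists were sparse and were not called by camera. Of 5 tested epithelial genes, 2 fell and none rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.0611), Epcam from 6.79 ± 0.213 to 1.94 ± 0.115 FPKM and Cdh1 from 4.95 ± 0.516 to 0.868 ± 0.0968 FPKM. The epithelial list passed without wild-type replicate 1 (adjusted p = 0.0166) or knockout replicate 1 (adjusted p = 0.0348). Of 3 tested B cell genes, 1 rose (1 adjusted over the list alone, camera adjusted p = 0.55), the immunoglobulin constant gene Ighm, from 44.8 ± 1.68 to 89.8 ± 5.11 FPKM. Of 3 tested endothelial genes, 1 rose (1 adjusted over the list alone, camera adjusted p = 0.939, with a median below and a mean above 0), Egfl7, at 7.76 ± 1.76 and 14.6 ± 2.77 FPKM, whose adjusted p of 0.0306 was as high as 0.122 with a library left out. The only tested neutrophil gene, Ly6g, was at 2.40 ± 0.0187 and 1.46 ± 0.0941 FPKM and passed only when adjusted over the list alone (camera adjusted p = 0.284). No tested gene passed, by limma or when adjusted over the list alone, among 2 fibroblast genes (camera adjusted p = 0.581) and 2 adipocyte and muscle genes (camera adjusted p = 0.763). The fibroblast list held Thy1, which T cells express, at 711 ± 60.9 and 780.1 ± 7.34 FPKM (adjusted p = 0.299), and Tagln at 1.10 ± 0.128 and 1.36 ± 0.411 FPKM (adjusted p = 0.551). The muscle genes Mylpf and Ckm were at 5.17 ± 0.407 and 4.91 ± 0.957 FPKM (adjusted p = 0.764) and at 2.40 ± 0.537 and 2.28 ± 0.328 FPKM (adjusted p = 0.857). No melanocyte gene reached the filter.

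The lists of ribosomal proteins, mitochondrially encoded genes, oxidative phosphorylation and the hypoxia response were called lower by camera. Of 62 tested cytosolic ribosomal protein genes, 26 fell and none rose (31 and 0 adjusted over the list alone), with a median log2 fold change of -0.29. Camera called that list lower (adjusted p = 3.77e-10), with an adjusted p of 0.241 with an estimated correlation and 0.278 after quantile normalization. Examples were Rps16, from 2042 ± 190 to 1008 ± 73.3 FPKM, and Rpl37, from 1221 ± 37.2 to 700.4 ± 28.7 FPKM. Rps23 fell from 3147 ± 242 to 1865 ± 67.3 FPKM and Rpl13a from 3555 ± 481 to 1770 ± 198 FPKM, and both calls were lost without knockout replicate 1 (adjusted p up to 0.0658). Of 13 tested mitochondrially encoded genes, 4 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.019, and adjusted p = 0.673 with an estimated correlation), and the list's median changed sign after quantile normalization (adjusted p = 0.942). Its adjusted p was 0.131 without wild-type replicate 2 and 0.0597 without knockout replicate 1. The complex I genes mt-Nd3, mt-Nd4 and mt-Nd6 fell from 2323 ± 590.4 to 1191 ± 20.8 FPKM, from 979.8 ± 119 to 696 ± 29.4 FPKM and from 569 ± 9.96 to 340.2 ± 22.4 FPKM. The ATP synthase gene mt-Atp8, which overlaps mt-Atp6, rose from 3738 ± 598 to 7853 ± 1188 FPKM. These 4 calls were lost without knockout replicate 1, with adjusted p up to 0.167. Of 44 tested nuclear genes of oxidative phosphorylation, 9 fell and 2 rose (8 and 2 adjusted over the list alone, camera adjusted p = 0.0346, and adjusted p = 0.491 with an estimated correlation). Its adjusted p was 0.0935 without wild-type replicate 1 and 0.126 without knockout replicate 1, and 0.196 after quantile normalization. Ndufa1, a complex I subunit gene, fell from 232 ± 16.9 to 109.6 ± 20.4 FPKM. Cox6c and Cox5b, of cytochrome oxidase, fell from 512 ± 36.6 to 312 ± 32.7 FPKM and from 363 ± 62.8 to 229 ± 8.93 FPKM, and Atp5j, of ATP synthase, from 230.4 ± 7.98 to 159.6 ± 9.95 FPKM. The calls of Cox6c, Cox5b and Atp5j were lost without knockout replicate 1, with adjusted p up to 0.111. Of 18 tested hypoxia response genes, 7 fell and 2 rose (8 and 2 adjusted over the list alone, camera adjusted p = 0.00939, and adjusted p = 0.241 with an estimated correlation). Ddit4, an inhibitor of mTOR signalling, fell from 258 ± 25.4 to 126 ± 8.22 FPKM, and Ankrd37 from 18.2 ± 0.777 to 8.53 ± 0.312 FPKM. Ndrg1 fell from 34.2 ± 2.83 to 16.8 ± 1.183 FPKM, and Ero1l, an oxidase of protein folding, from 50.1 ± 2.62 to 33.6 ± 0.757 FPKM, a call lost without either knockout library (adjusted p up to 0.0861).

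Lists of glycolysis, sterol synthesis, apoptosis, heat shock and the interferon response were not called by camera. Of 20 tested glycolysis genes, 2 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.537). The lactate carrier genes Slc16a1 and Slc16a3 went in opposite directions, from 29.8 ± 1.14 to 41.1 ± 0.318 FPKM and from 169 ± 17.5 to 118 ± 5.07 FPKM, and the phosphofructokinase gene Pfkl rose from 63.4 ± 3.20 to 80.5 ± 5.57 FPKM. Of 21 tested sterol synthesis genes, 3 rose and 1 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.22). The cholesterol synthesis gene Dhcr7 rose from 19.4 ± 2.94 to 27.4 ± 0.206 FPKM, and Msmo1, of the same pathway, fell from 47.8 ± 2.72 to 36.8 ± 2.71 FPKM. Of 21 tested apoptosis regulators, 2 rose and 4 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.21). The survival gene Mcl1 fell from 128 ± 8.45 to 84.7 ± 6.11 FPKM and the death gene Bbc3 from 51.3 ± 12.7 to 23.4 ± 0.837 FPKM, while Trp53, which encodes p53, rose from 121 ± 0.306 to 157 ± 0.415 FPKM. Of 20 tested heat shock and unfolded protein genes, 3 rose and 3 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.581), with a median above and a mean below 0. The chaperone genes Hspd1 and Hsp90b1 rose from 264 ± 14.7 to 371 ± 7.58 FPKM and from 289 ± 10.2 to 367 ± 3.81 FPKM, and Dnajb4 and the stress factor gene Ddit3 fell from 5.46 ± 0.239 to 2.91 ± 0.228 FPKM and from 30.4 ± 0.216 to 18.7 ± 3.31 FPKM. Of 34 tested interferon response genes, 9 rose and 4 fell (10 and 5 adjusted over the list alone, camera adjusted p = 0.581). Igtp, an interferon-induced GTPase gene, rose from 130 ± 0.0269 to 236 ± 0.239 FPKM (adjusted p = 0.00282). A second such gene, Iigp1, rose from 12.7 ± 0.263 to 19.6 ± 0.967 FPKM, while the exonuclease gene Isg20 fell from 34.4 ± 2.72 to 21.5 ± 1.23 FPKM and Socs1, an inhibitor of cytokine signalling, from 168 ± 24.3 to 102 ± 0.285 FPKM. Of the genes named from these 5 lists, all but Igtp had calls that were lost with at least 1 knockout library left out, with adjusted p up to 0.27.

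The remaining genes of the largest rises lay mainly on the sex chromosomes. Eif2s3y and Ddx3y, on chromosome Y, rose from 3.36 ± 0.665 to 19.5 ± 2.86 FPKM (log2 fold change 2.23, SE 0.16, adjusted p = 0.00221) and from 1.09 ± 0.296 to 6.86 ± 0.304 FPKM (log2 fold change 1.92, SE 0.15, adjusted p = 0.00266). Mid1, a microtubule-associated gene on chromosome X, rose from 3.01 ± 0.857 to 10.2 ± 0.469 FPKM, and Tgfbr3l, on chromosome 8, from 2.46 ± 0.290 to 8.07 ± 1.604 FPKM. Among 126 named genes past the threshold besides Map4k1, 84 passed with each library left out in turn, and 42 lost the call in at least 1 such fit.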

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

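Removal of a length and GC trend was added after seeing the data, and every other alternative was fixed beforehand. No named gene or list that was called turned into a call in the other direction under any alternative run. The median of mitochondrial genes, called lower, changed sign after quantile normalization (0.0194), where the list was not called. Count-based alternatives were not run, since the values were FPKM. Of 137 named genes tested besides Map4k1, 133 or more kept their side of the threshold under each other pseudocount and each other scaling, and 132 with the trend on length and GC removed. Leaving out a library, from wild-type replicates 1 and 2 to knockout replicates 1 and 2, ended the calls of 8, 6, 40 and 35 of them. Without a filter on low values 37 calls were lost, in a fit that had more tests and also another variance trend. On the scale given by the steps between low values, a single fragment in a 2-kb gene was worth 0.0247 to 0.0284 FPKM. Genes near 0 thus carry a counting error of a few fragments.

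The count of changed genes was 3390 and ranged from 579 to 3235 with a library left out, with 189 to 1693 higher and 390 to 1542 lower; knockout replicate 1 gave the lowest values. Without the filter it was 1231, with 609 higher and 622 lower. Requiring a 2-fold change as well gave 508, with 114 higher and 394 lower. Map4k1 stayed at -0.91 in both of these but missed them, with an adjusted p of 0.0764 without the filter and a change under 2-fold. It ranged from -1.09 to -0.74 with a library left out, with adjusted p from 0.0244 to 0.0634. Scaling to equal totals gave 3475 higher and 1118 lower genes, and median-of-ratios scaling 1527 higher and 1726 lower, so the balance of calls depends on the scaling.

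With an estimated correlation, camera called 0 lists, 0 higher and 0 lower, in place of 20. That setting rests on the 2 residual degrees of freedom, and its smallest unadjusted camera p was 0.0224, for chemokines. The cell cycle list had 0.0332 there, against 8.36e-20 at the preset correlation. After adjustment over 35 lists a call was thus unlikely even for a strong shift. The missing calls therefore do not show that correlation between genes accounts for the list results. The adjusted p was 0.185 for the inhibitory receptor, cytotoxic, cytokine, chemokine, NF-kappa B, MHC class II and cell cycle lists, 0.186 for regulatory T cells, 0.204 for MAPK and AP-1, and 0.206 for CD4 T cells and dendritic cells. It was 0.241 for hypoxia and ribosomal proteins, 0.254 for mast cells, 0.36 for gamma delta and NK cells, 0.376 for erythroid genes, 0.427 for macrophages and costimulation, 0.491 for oxidative phosphorylation and 0.673 for mitochondrial genes. With fry, 4 lists were called higher, and interferon response, sterol synthesis and heat shock passed (each 0.0219), as did CD8 T cells (0.00322), neutrophils (0.015) and epithelial genes (0.0172), while oxidative phosphorylation (0.185) and mitochondrial genes (0.215) did not. Camera and fry test different hypotheses.

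Among the lists near the threshold, oxidative phosphorylation lost its call without the filter (0.0588), after quantile normalization (0.196) and with the trend removed (0.535). Its range with a library left out was 0.0156 to 0.126. Mitochondrial genes lost theirs after quantile normalization (0.942) and with the trend removed (0.484), with a range of 0.000288 to 0.131. Ribosomal proteins lost theirs after quantile normalization (0.278) and erythroid genes with the trend removed (0.0591). Costimulation lost its call with the stricter filter (0.0501) and quantile normalization (0.0524), with a range of 0.017 to 0.111, and macrophages with the stricter filter (0.105), with a range of 0.0122 to 0.0522. Epithelial genes ranged from 0.0166 to 0.297. Without the filter, sterol synthesis (0.0455) and neutrophil genes (0.00853) passed, so that 2 lists were called higher. Oxidative phosphorylation also lost its call with equal totals (0.263) and with limma without the trend (0.0516), and both let epithelial genes pass (0.0342 and 0.0489). The highest correlation between genotypes was 0.952 over genes with a mean of at least 5 FPKM in place of 0.964. The cause of these changes was not tested.

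The libraries of both genotypes are numbered 1 and 2, but no label says that a number pairs them, and their deviations from the genotype means had a correlation of -0.0321. With the replicate number as a block, the paired fit called 2801 genes, with 1453 higher and 1348 lower, and 2 of the 137 named genes lost their call.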

Other observations

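The families in this paragraph were chosen after their values were seen and were not tested for enrichment, and 28.4% of all tested genes passed. Of 105 tested T cell receptor alpha variable segments, 31 rose and none fell, and their summed FPKM went from 1046 and 1041 in wild type to 1756 and 1663 in the knockout. Of 22 tested beta variable segments, 4 fell and none rose. The largest beta segment was Trbv29 in both wild-type libraries and Trbv14 in both knockout libraries. Trbv29 held 12.1% and 10.5% of beta variable FPKM in wild type and 9.08% and 8.99% in the knockout, and Trbv14 held 7.60% and 9.14% in wild type and 10.4% and 11.1% in the knockout. Segments share similar sequence, so single values are uncertain. Of 8 tested killer lectin-like receptor genes (Klr), 5 fell and 1 rose, of 9 serpins 6 fell and none rose, and of 8 S100 calcium-binding genes 6 fell and none rose. Of 24 kinesin genes (Kif), which include motors of the mitotic spindle, 13 rose and 1 fell. Of 54 histone genes named Hist, 14 rose and 5 fell.

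Calls did not gather around the targeted gene. Of 213 tested genes within 10 Mb of Map4k1 on chromosome 7, 27.7% passed, against 28.4% elsewhere (odds ratio 0.966, two-sided Fisher's exact test, p = 0.878, genes not being independent). The processed pseudogenes Gm28900 and Gm9836 were chosen after their values were seen. They were listed at 0 in both wild-type libraries and at 296.8 and 838.6 FPKM and 38.4 and 24.9 FPKM in the knockout libraries. Estimates for such short genes can fail, and no fold is given.

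In the next 3 paragraphs, the tests of other leukocytes, of exchanged labels and both tests of Y-linked genes were chosen after the result was seen. The predictions for receptor stimulation and for length and GC were written before the outcome of their own tests. The length and GC fit itself was added after the data were seen.

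The first pattern is the fall of cytokine, chemokine and granule genes. If macrophages, dendritic cells, B cells or NK cells had brought these transcripts into the wild-type libraries, abundant genes of those cells should have fallen with them. The 33 called genes fell by 6769 FPKM in sum. The 20 abundant genes that were measured (of 26 listed, such as Lyz2, Cst3, Cd74, Ncr1 and Fcer1g) fell by 98.9 FPKM, net of a rise of Ighm. The ratio of 0.0146 argues against macrophages, dendritic cells and B cells as the main source of the summed fall. That sum is weighted to abundant genes such as Gzmd. For NK cells the ratio cannot decide, since their listed genes were far less abundant than Gzmd in these libraries. The highest of them, Fcer1g, averaged 60.0 FPKM in wild type, against 1331 FPKM for Gzmd. Fcer1g, Klrb1c, Tyrobp and Klra7 were lower in the knockout libraries, so NK cells stay open as a source. The ratio cannot decide the source of low genes such as Ccl22 and Ccl17, since Cd74, H2-Aa and H2-Eb1 also fell, while Apoe and Cd79b did not. Lyz2 was at most 0.0491 FPKM and Ncr1 at most 0.0821 FPKM, while Cst3 and Fcer1g, which T cells can also express, had the largest falls among the 20. Exchanged genotype labels are argued against by Map4k1, with a log2 fold change of -0.911. This argument is limited, since the allele was not described and the transcript level need not follow the genotype. A biological hypothesis is that the knockout T cells had received less recent receptor stimulation, and 14 of 27 tested stimulation-induced genes outside the fixed lists fell and none rose; their median of -0.453 lay below all 10000 random lists matched on mean expression, but it missed the bound of -0.5 set in advance, so this stays open, as does a different mix of T cells.

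The second pattern is the rise of cell cycle genes and the fall of ribosomal protein genes. Long transcripts tended to be higher in the knockout, with a Spearman correlation across 11904 genes of 0.2 between fold change and transcript length, against 0.185 and -0.174 for replicate 2 minus 1 in wild type and knockout; with GC content it was -0.0554, against -0.443 and -0.0569, so the wild-type libraries differed most by GC. With the trend on length and GC removed per library, the cell cycle list kept a median log2 fold change of 0.687 (0.766 before), and 41 of its 44 genes rose. The ribosomal list kept -0.213 (-0.295 before), close to the bound set in advance, and 22 of its 62 genes fell. The trend as fitted therefore did not account for all of either change. Length was taken from the longest annotated transcript, with a median of 1124 nt for the ribosomal list, which need not be the one expressed. A larger length effect on the ribosomal genes thus stays open. For the ribosomal genes a difference in the overall distribution of high values may contribute, since quantile normalization brought camera's adjusted p to 0.278 and the median to -0.0489, whereas the cell cycle median stayed at 0.732; a genotype effect on either list is open.

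The third pattern is the rise of Y-linked genes. Eif2s3y, Ddx3y, Kdm5d and Uty (the last 2 chosen after their values were seen) had 5.80, 6.30, 7.90 and 5.17 times the mean FPKM in the knockout, and all were above 0 in both wild-type libraries. Reads from X-linked homologues are argued against, since the log2 ratio of the Y-linked gene exceeded that of its homologue by a median of 2.41, although Ddx3x itself rose. A larger share of male cells in the knockout libraries is a candidate explanation, since the 4 ratios lay within a factor of 1.53 of each other. Xist, which female cells express, was at 66.9 and 81.2 FPKM in wild type and 68.2 and 64.4 FPKM in the knockout (limma adjusted p = 0.351). Female cells were therefore present in all 4 libraries, and a male share, if any, may have been small. If the share of male cells did differ, it changed along with genotype. The comparison cannot separate such a difference from an effect of the knockout, for any of the called genes. Whether any male cells came from the host or from pooled animals was not tested.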
